A study of Mus musculus with 9 samples.

How the data were processed

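RNA from the cortex of wild-type CD1 mouse embryos at embryonic days 12 to 13 was measured as total input, after precipitation with nonspecific IgG and after precipitation with an antibody to Pum2, in 3 biological replicates each. Per the labels' protocols, precipitates were made with a commercial kit for RNA-binding proteins, RNA was extracted with phenol and chloroform, amplified with a kit for small amounts, labelled and hybridised to the Mouse Gene 2.0 ST array. Per the submitters' processing notes, the log2 values were made with the RMA method in Affymetrix Expression Console before they were deposited. RMA corrects background, normalizes the arrays and summarises probes. The versions are not given in the sources used here. No depth applies to arrays, and precision is set by the number of arrays and by signal over background.

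The deposited table holds 41345 features on 9 arrays. Of these, 23521 carry exactly 1 gene symbol, 1814 carry several and 16010 are unnamed here. Names came from the probe table given with the series and were checked against RefSeq gene names of GRCm38.p6, in which 23328 of the Entrez identifiers occur and no symbol needed an update. The build used by the authors is not given in the sources used here. Each gene was read from its feature with the highest mean over all arrays, which left 22180 genes. Of the 1082 genes with more than 1 feature, 14, 18 and 3 had features called in opposite directions in Pum2 over IgG, Pum2 over input and IgG over input, and none of them is named in the text. Genes with no feature carrying a single symbol were left out of the comparisons of genes, and such features were only counted. Probes of ribosomal protein genes, histone genes and other close paralogs can cross-hybridise, so values of single members of these families are less certain. The array median over genes lay between 6.06 and 6.10, and no further normalization was applied. In 2 genes no group showed any spread, and 890 genes had fewer than 6 distinct values over the 9 arrays.

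The comparisons were Pum2 over IgG (the main control), Pum2 over input, IgG over input, and the genes past the threshold in the same direction against both controls. Genes were tested with limma 3.58.1 in R 4.3.3, in 1 fit of all 9 arrays with 3 groups, 6 residual degrees of freedom, no replicate block and the default prior. P-values were adjusted by the method of Benjamini and Hochberg over the 22180 genes, and called below an adjusted p of 0.05 with no fold threshold. They measure spread between arrays labelled as biological replicates. An exact permutation test of 3 against 3 arrays gives no p below 0.1, so calls rest on the moderated spread of limma. A value given with ± is the log2 difference and its standard error.

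The 26 gene lists were written from general knowledge before the data were examined. They were tested by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 26 lists of a comparison. The test was repeated with the correlation estimated from the arrays, a setting that changes p by more than the correlation alone. Lists were also tested with fry (statmod 1.5.0), whose p is that of a self-contained test of direction. For each list the text gives genes called over all genes and genes called when p-values are adjusted over the list alone. Shares of genes higher than both controls were compared by Fisher's exact test, two-sided, among genes at or above the median signal, adjusted over the 26 lists. The overlap of the comparisons that share the Pum2 arrays is given beside 100 simulations of unchanged arrays, which hold no effects, and the overlap of independent lists of the same sizes.

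Named genes follow a rule. For each comparison and for the set over both controls, they come from the 10 largest positive and 10 largest negative log2 differences among genes past the threshold whose 3 against 3 arrays do not overlap. Provisional names and small RNA families, 4988 genes, and genes with a mean below the median of 6.08, a further 6823, were left out. The set over both controls was ranked by the smaller difference. Up to 4 members of each list and comparison with the largest moderated t were added, and Pum2, Eif4enif1, Pou3f3, Tle4, Neurog1 and Neurog2 were always included. Not all genes the rule allows are named.

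The pipeline was tested on simulated data with 200 changed genes among 22180. In both Pum2 comparisons 91% of genes changed by a log2 difference of 1 were called. Of genes changed by 0.5, 45% were called against IgG and 48% against input. False calls numbered 8 and 9, and 0 in IgG over input, where no gene was changed. Many more genes were called in the data, 6815 against IgG and 7688 against input. The adjustment of p-values then differs, so these rates need not hold for the real arrays.

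Alternatives were a replicate block, only the groups compared in the fit, only genes at or above the median level, an intensity trend with a robust prior, quantile normalization run again, centring on the brighter genes, array weights, the mean over the features of a gene, all features of the table, fold thresholds, and each array left out in turn. A test of the Pumilio recognition motif in 3' untranslated regions was planned and not run, since it needs transcript sequences. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.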

Results

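The study asked which transcripts of the developing mouse cortex are held by Pum2, a Pumilio-family protein that binds mRNA and represses its translation, and its title ties such a repressive complex to the specification of neurons from neural stem cells. Cortices were taken from wild-type CD1 embryos at embryonic days 12 to 13, when radial precursors, the stem cells of the cortex, are making the first neurons. RNA was precipitated from the lysate with an antibody to Pum2 or with nonspecific IgG, the background of the method, and total RNA from the same kind of tissue served as input. Each of the 3 kinds of RNA was hybridised as 3 biological replicates, 9 arrays in all, to the Mouse Gene 2.0 ST array, and 22180 genes with a name of their own were compared. The values were log2 signals. Across genes, which are not independent replicates, the arrays of a group correlated with Pearson r between 0.994 and 0.996. Between groups, r was 0.988 to 0.989 for IgG against input, 0.98 to 0.984 for Pum2 against IgG and 0.977 to 0.979 for Pum2 against input. The median SD between replicates was 0.11 in input, 0.12 in IgG and 0.10 in Pum2 precipitates (log2, n = 3 each). The array median over all features was 5.37 to 5.40 in the Pum2 precipitates and 5.48 to 5.57 in the other arrays. An array gives no read depth, and the number of arrays limits the precision.

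The genes of this paragraph, regulators of neuronal specification and of translation, were named in advance, and some other specification genes, such as Neurod6 and Cux1, were lower with Pum2 than in either control. Neurog1 and Neurog2, the proneural factors that start the making of excitatory cortical neurons, were higher in the Pum2 precipitate than in IgG by 0.96 ± 0.10 and 0.52 ± 0.08 (log2 difference ± SE, n = 3 arrays per group, limma adjusted p = 5.76e-05 and 5.68e-04), and higher than in input by 0.82 ± 0.10 and 0.66 ± 0.08 (adjusted p = 9.35e-05 and 9e-05). Neither passed the test in IgG over input (-0.14, adjusted p = 0.388, and 0.14, adjusted p = 0.276). Eif4enif1, which encodes the translational repressor 4E-T, rose by 0.79 ± 0.09 over IgG and 1.00 ± 0.09 over input (adjusted p = 1.23e-04 and 1.8e-05), which is 1.73-fold and 2.00-fold. Tle4, a corepressor of deep-layer neurons, rose by 0.41 ± 0.10 over IgG and 0.74 ± 0.10 over input (adjusted p = 0.0122 and 2.72e-04). Pou3f3, a transcription factor of upper-layer neurons, rose over input (0.32 ± 0.08, adjusted p = 0.0104) but differed from IgG by less than the test could tell from the spread (0.08 ± 0.08, adjusted p = 0.491). The Pum2 transcript itself rose by 0.91 ± 0.09 over input (adjusted p = 3.41e-05), and by 0.61 ± 0.09 in IgG over input (adjusted p = 0.00148). Its difference from IgG was smaller, 0.30 ± 0.09 (adjusted p = 0.0314), and was not past the threshold when each array was centred on the brighter genes (0.20) or when input was left out of the fit (0.30). The same call ended without IgG replicate 1 (0.25), IgG replicate 3 (0.29), Pum2 replicate 1 (0.24) or Pum2 replicate 2 (0.28).

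**Figure D1:**
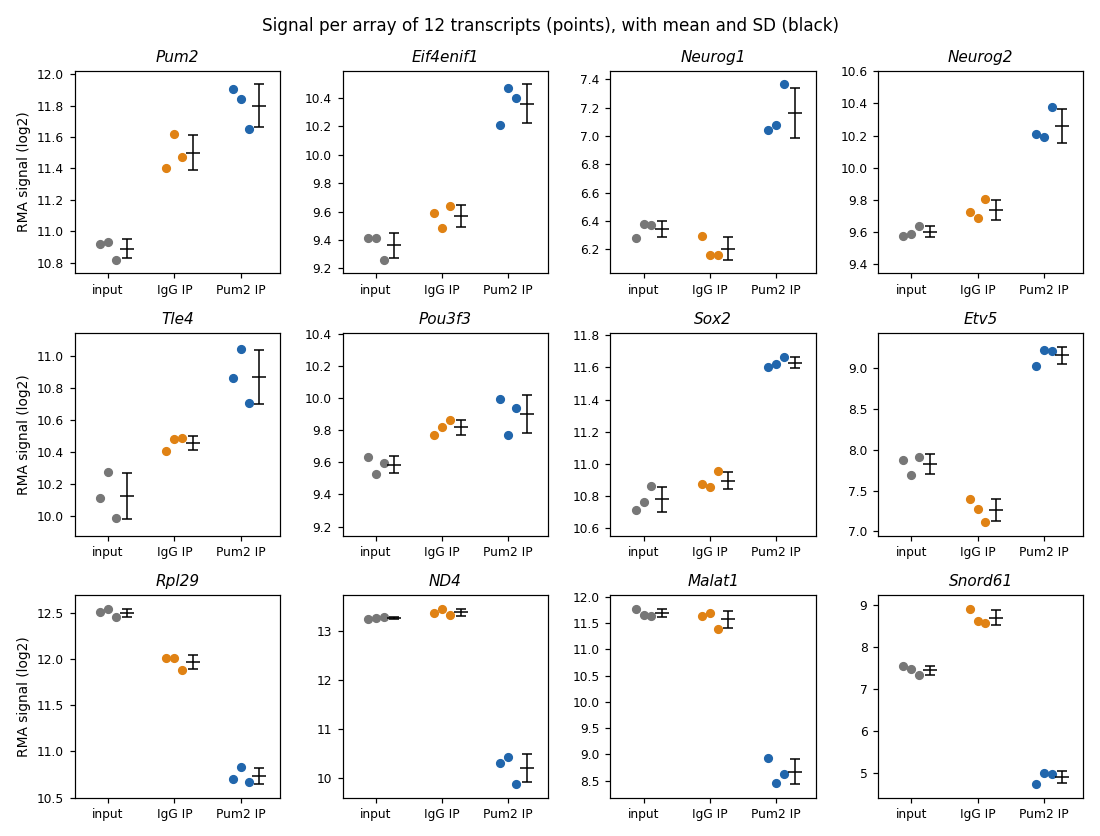
Deposited log2 signal of 12 transcripts on each of the 9 arrays (points, coloured by group), with the mean and SD of the 3 arrays of a group in black; each panel has its own vertical axis, which does not start at 0. The Pum2 points of Eif4enif1 (10.208 to 10.471) lie above all IgG points (9.483 to 9.636) and input points (9.26 to 9.415), and those of ND4 (9.878 to 10.439) lie below all others (13.262 to 13.465).

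Against nonspecific IgG, the main control, the most enriched transcript of the Pum2 precipitate was that of Etv5, an ETS transcription factor induced by fibroblast growth factor signalling (1.90 ± 0.10, 3.72-fold, adjusted p = 2.18e-06). Among the next were Ifngr1, a subunit of the interferon gamma receptor (1.501 ± 0.10), Sesn2, a stress-induced regulator of growth signalling (1.40 ± 0.08), Rab6b, a small GTPase of Golgi traffic (1.37 ± 0.09), and Rtl6, a gene derived from a retrotransposon (1.36 ± 0.10). Among the most depleted were transcripts made inside mitochondria. ND3, ND2, ND4L and CYTB, subunits of the respiratory chain, fell, with differences of -4.43 ± 0.17, -4.41 ± 0.19, -4.35 ± 0.15 and -3.55 ± 0.14. ND3 was 21.5-fold lower (adjusted p = 3.36e-07). Rpph1, the RNA of the tRNA-processing enzyme RNase P, and Malat1, a long noncoding RNA of nuclear speckles, also fell (-4.38 ± 0.16 and -2.90 ± 0.13, adjusted p = 2.4e-07 and 7.67e-07). Of 22180 genes, 4296 (19.4%) were higher and 2519 (11.4%) lower with Pum2 (limma, adjusted p under 0.05). Changes of at least 1.5-fold numbered 1448 and 1106, and changes of at least 2-fold 145 and 382. The 3 arrays of one group lay wholly above or below those of the other for 41.3% of genes, where chance gives 10%. The share of calls that were higher, 63%, depended on the scaling of the arrays. It was 46.9% with arrays centred on the brighter genes, and 79.1% with quantile normalization run again, which took the median of all genes from 0.04 to 0.19. Over all features of the table, unnamed ones included, lower calls were the more frequent, 6481 against 4877 higher.

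Transcripts reported elsewhere as Pumilio targets, a list drawn up from knowledge of other studies, rose as a group. Of 22 measured, 16 were higher and 1 lower than in IgG (18 and 1 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 1.19e-05). The call held with an estimated correlation between genes (adjusted p = 0.0341). Examples were Cks2, a cyclin-dependent kinase subunit (1.00 ± 0.11), Rheb, an activator of mTOR (0.95 ± 0.07), the Wnt receptor gene Fzd8 (0.75 ± 0.07) and the cyclin gene Ccng2 (0.61 ± 0.07). Among radial precursor genes, 13 of 22 rose and 2 fell (14 and 2 adjusted over the list alone), with a median of 0.35 (adjusted p = 3.33e-04, but 0.051 with an estimated correlation). The stem cell factor Sox2 rose by 0.73 ± 0.07, Id4 by 0.70 ± 0.08, the receptor kinase Ddr1 by 0.66 ± 0.07 and the Notch effector Hes1 by 0.64 ± 0.07. In the Wnt pathway 21 of 32 genes rose and 2 fell (22 and 2 adjusted over the list alone; median 0.40, adjusted p = 8.22e-05, but 0.0787 with an estimated correlation). Fzd1 rose by 1.02 ± 0.09, Axin1 by 0.83 ± 0.11 and Dvl2 by 0.81 ± 0.11. In the Notch pathway 16 of 24 rose and 2 fell, counts that were the same adjusted over the list alone (median 0.40, adjusted p = 8.95e-04, but 0.337 with an estimated correlation). The gamma-secretase subunit gene Ncstn rose by 1.24 ± 0.08 and the coactivator Maml1 by 0.95 ± 0.07, whereas Mfng, which modifies Notch receptors, fell by 0.84 ± 0.09. Rises of this size were not limited to precursor genes, since endothelial and meningeal lists had medians of 0.41 and 0.39.

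Of 33 cell-cycle genes, 20 rose and 5 fell against IgG, also when adjusted over the list alone (median 0.36, adjusted p = 0.00449, but 0.464 with an estimated correlation). The replication licensing factor Cdt1 rose by 0.99 ± 0.08 and the mitotic kinase gene Cdk1 by 0.64 ± 0.08. Mki67, a marker of dividing cells, fell by 1.00 ± 0.07, the spindle checkpoint kinase gene Bub1 by 1.01 ± 0.10 and E2f1 by 0.74 ± 0.08. Of 43 axon guidance and adhesion genes, 16 rose and 1 fell, again the same adjusted over the list alone (median 0.18, adjusted p = 0.0152, but 0.42 with an estimated correlation). Examples were Unc5a (1.049 ± 0.08), Efnb1 (1.04 ± 0.08) and Unc5b (0.99 ± 0.10). Without IgG replicate 1 the median of this list was 0.14 and the call ended.

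No shift against IgG was found by the set test for the lists of neuronal identity. Of 18 proneural and neuronal-commitment factors 4 rose and 6 fell (4 and 7 adjusted over the list alone; median -0.07, adjusted p = 0.448), and Neurod6, a factor of young neurons, fell by 0.76 ± 0.11. Deep-layer specification genes gave 5 higher and 4 lower of 17 (5 and 6 adjusted over the list alone; median -0.08, mean 0.04, test towards lower, adjusted p = 0.485). Lmo3 rose by 0.83 ± 0.08 and Foxp2 fell by 0.59 ± 0.08. Upper-layer specification genes gave 2 and 2 of 13 (3 and 2 adjusted over the list alone; median 0.06, test towards lower, adjusted p = 0.906). Pou3f1 rose by 0.68 ± 0.08 and Cux1 fell by 0.82 ± 0.10. Neuronal structure genes gave 8 and 4 of 26 (11 and 4 adjusted over the list alone; median 0.13, adjusted p = 0.372). Crmp1, which acts in growth cones, rose by 1.28 ± 0.09 and Gap43 fell by 0.62 ± 0.10. The machinery of 4E-T, Pumilio and mRNA silencing gave 12 and 7 of 35 (15 and 8 adjusted over the list alone; median 0.06, adjusted p = 0.776). Transcripts of the deadenylase subunit Cnot8 rose (0.83 ± 0.09), while those of Cnot6, of the poly(A)-binding protein Pabpc1 and of the RNA transport factor Stau2 fell by 0.84 ± 0.07, 0.97 ± 0.08 and 0.98 ± 0.07. Chromatin regulators gave 7 and 6 of 36, also adjusted over the list alone (median 0.04, test towards lower, adjusted p = 0.83). Smarcb1 of these rose by 0.76 ± 0.09. Ubiquitin E2 and E3 genes gave 10 and 8 of 37 (11 and 11 adjusted over the list alone; median 0.02, test towards lower, adjusted p = 0.752). Trim32 of these rose by 0.65 ± 0.08.

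The lists with the lowest medians against IgG were mitochondrially encoded genes and small nucleolar RNAs. All 10 mitochondrially encoded genes were lower than in IgG, with a median of -3.27 (camera adjusted p = 3.62e-17, but 0.051 with an estimated correlation). Of 78 small nucleolar RNAs, guides of rRNA modification in the nucleolus, 58 fell and 0 rose (60 and 0 adjusted over the list alone; median -1.048, adjusted p = 1.45e-33, and 0.0341 with an estimated correlation). At an unadjusted p under 0.05 and a positive difference there were also 0. Snord61, Snora23 and Snord104 fell most among those named here (-3.80 ± 0.11, -3.72 ± 0.16 and -3.34 ± 0.10). Of 13 nuclear and imprinted long noncoding RNAs 5 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.27, adjusted p = 3.8e-05, and 0.0341 with an estimated correlation). Miat fell by 1.54 ± 0.12 and Snhg1 by 1.47 ± 0.08. Ribosomal protein mRNAs fell in 30 of 67 cases and rose in 5 (31 and 5 adjusted over the list alone; median -0.20, adjusted p = 1.05e-07, but 0.0609 with an estimated correlation). Rpl29 fell by 1.23 ± 0.08 and Rps12 by 1.17 ± 0.07. Nuclear-encoded oxidative phosphorylation genes went both ways, 22 of 71 down and 15 up (24 and 15 adjusted over the list alone; median -0.08, adjusted p = 0.013, but 0.579 with an estimated correlation). The complex I genes Ndufc1 and Ndufs7 stood at -1.56 ± 0.07 and 0.92 ± 0.08, and the call of this list ended without IgG replicate 1 (median -0.06). Histone genes were picked by name, linker histone genes such as H1f10 included, and their probes can cross-hybridise. They gave 7 higher and 2 lower of 29, also adjusted over the list alone (median 0.16, camera adjusted p = 0.455).

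**Figure D2:**
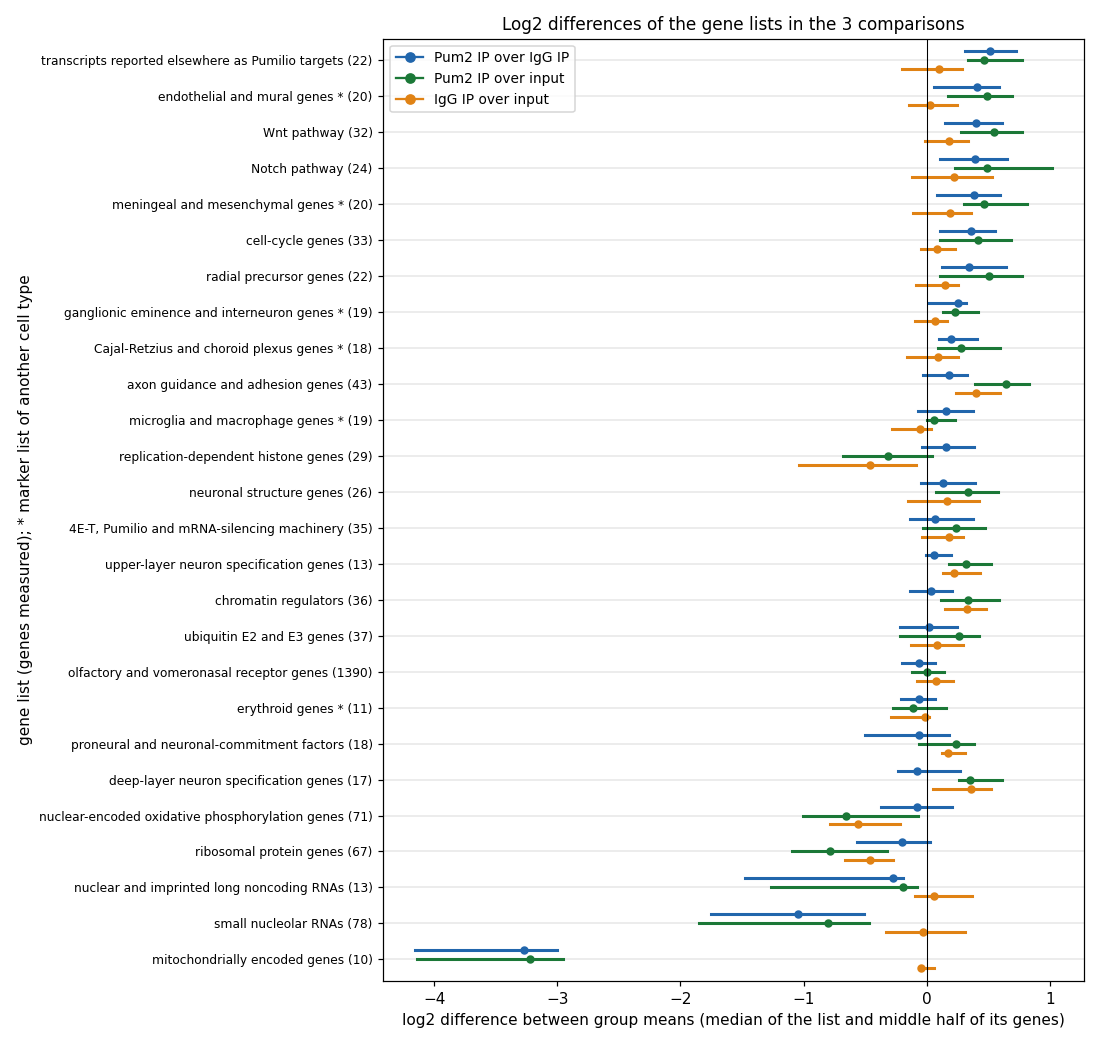
Log2 differences of the 26 gene lists in the 3 comparisons, with 1 row per list and the number of genes measured in brackets; points are medians over the genes of a list, bars span its interquartile range, and an asterisk marks lists of other cell types. The mitochondrially encoded genes lie at -3.27 and -3.22 in both Pum2 comparisons and at -0.04 in IgG over input.

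Compared with input, total RNA from the same kind of tissue, the Pum2 precipitate was richest in transcripts of Nr4a1, an early-response nuclear receptor (1.503 ± 0.10, 2.83-fold, adjusted p = 2.24e-06). Other examples were the forkhead factor Foxq1 (1.49 ± 0.12), the natriuretic peptide receptor Npr2 (1.47 ± 0.13), Gclc, an enzyme of glutathione synthesis (1.43 ± 0.08), Syvn1, a ubiquitin ligase of the endoplasmic reticulum (1.42 ± 0.08), and the Hedgehog receptor Ptch1 (1.41 ± 0.14). Among the lowest were Rpph1 at -5.45 ± 0.16, the mitochondrial transcript ND3 at -4.95 ± 0.17 and the Y RNA Rny1 at -4.24 ± 0.25 (Rpph1 and Rny1, adjusted p = 5.51e-08 and 1.45e-06). The membrane protein gene Tlcd1 fell by 3.36 ± 0.09. Higher genes numbered 4793 (21.6%) and lower genes 2895 (13.1%), of which 1844 and 1547 changed at least 1.5-fold and 237 and 675 at least 2-fold. Arrays of the groups did not overlap for 45.3% of genes, against 10% by chance. The share of calls that were higher was 62.3%, and 52.2% with centring on the brighter genes or 76.6% with quantile normalization run again, which took the median of all genes from 0.07 to 0.19. With all features of the table counted, 5319 were higher and 6601 lower.

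More lists shifted against input than against IgG, 21 against 14 of 26 by camera, and 5 against 4 with an estimated correlation. A difference between those numbers was not tested. Axon guidance and adhesion genes rose in 36 of 43 cases and fell in 0 (37 and 0 adjusted over the list alone; median 0.65, adjusted p = 2.17e-13, and 0.0436 with an estimated correlation). Unc5b rose by 1.33 ± 0.10 and Plxna1 by 1.03 ± 0.10. Part of the rise of this list was also seen with nonspecific IgG, whose median over input was 0.40. In the Wnt pathway 22 of 32 rose and 0 fell (25 and 0 adjusted over the list alone; median 0.54, adjusted p = 1.54e-07, and 0.0436 with an estimated correlation). Fzd8 rose by 1.25 ± 0.07. Of the reported Pumilio targets 16 of 22 rose and 1 fell (18 and 2 adjusted over the list alone; median 0.47, adjusted p = 4.02e-05, and 0.0436 with an estimated correlation). E2f3 of these rose by 0.92 ± 0.07. Ribosomal protein mRNAs fell in 54 of 67 cases and rose in 3, also adjusted over the list alone (median -0.78, adjusted p = 7.93e-26, and 0.0205 with an estimated correlation). Small nucleolar RNAs fell in 55 of 78 and rose in 0 (60 and 0 adjusted over the list alone; median -0.80, adjusted p = 5.78e-28, and 0.0289 with an estimated correlation). The other calls against input were lost with an estimated correlation. Radial precursor genes rose in 16 of 22 cases and fell in 3, also adjusted over the list alone (median 0.50, adjusted p = 3.61e-04, but 0.0538 with an estimated correlation). Sox1 rose by 0.99 ± 0.09 while Tead2 fell by 0.76 ± 0.07. Notch pathway genes gave 17 and 3 of 24 (18 and 3 adjusted over the list alone; median 0.49, adjusted p = 2.52e-04, but 0.154 with an estimated correlation). The Notch ligand gene Jag1 rose by 1.35 ± 0.11. Cell-cycle genes gave 21 and 3 of 33 (22 and 3 adjusted over the list alone; median 0.42, adjusted p = 3.61e-04, but 0.253 with an estimated correlation). The mitotic kinase gene Plk1 rose by 0.92 ± 0.10.

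Of 4 neuronal lists, 3 passed camera as higher than input, and none with an estimated correlation. Nonspecific IgG also raised these 3 over input, with medians of 0.36 (deep-layer), 0.22 (upper-layer) and 0.16 (neuronal structure). Their rises over input are therefore not particular to Pum2. Deep-layer genes gave 11 higher and 2 lower of 17 (13 and 2 adjusted over the list alone; median 0.35, adjusted p = 0.00346, but 0.108 with an estimated correlation). Tbr1 rose by 0.87 ± 0.08. Upper-layer genes gave 7 and 1 of 13, also adjusted over the list alone (median 0.32, adjusted p = 0.0196, but 0.131 with an estimated correlation). Neuronal structure genes gave 15 and 4 of 26 (16 and 4 adjusted over the list alone; median 0.33, adjusted p = 0.0108, but 0.387 with an estimated correlation). The adhesion molecule gene L1cam rose by 1.195 ± 0.10. Proneural factors gave 8 and 3 of 18 (9 and 4 adjusted over the list alone; median 0.24, adjusted p = 0.238). Chromatin regulators gave 22 and 1 of 36 (25 and 1 adjusted over the list alone; median 0.33, adjusted p = 2.17e-05, but 0.108 with an estimated correlation). Kmt2d, a histone methyltransferase gene, rose by 1.098 ± 0.07. The chromatin list had a median of 0.33 in IgG over input too. The silencing machinery gave 17 and 5 of 35 (20 and 5 adjusted over the list alone; median 0.24, adjusted p = 0.0444, but 0.297 with an estimated correlation). The decapping scaffold gene Edc4 rose by 1.04 ± 0.10. The call of this list also ended without input replicate 1 (median 0.22), input replicate 2 (0.23) or Pum2 replicate 1 (0.22), with only the brighter genes (0.24) and with quantile normalization run again (0.28). A replicate block ended it too (0.242). Ubiquitin genes gave 19 and 6 of 37 (20 and 10 adjusted over the list alone; median 0.26, adjusted p = 0.32). Lower than input were oxidative phosphorylation genes, with 51 of 71 down and 9 up (51 and 10 adjusted over the list alone; median -0.66, adjusted p = 9.52e-18, but 0.0623 with an estimated correlation). Histone genes followed, with 12 of 29 down and 1 up, also adjusted over the list alone (median -0.32, adjusted p = 3.35e-04, but 0.108 with an estimated correlation). All 10 mitochondrially encoded genes fell (median -3.22, adjusted p = 8.29e-16, but 0.0546 with an estimated correlation). Long noncoding RNAs had 6 of 13 down and 3 up, also adjusted over the list alone (median -0.20, adjusted p = 0.00704, but 0.0677 with an estimated correlation).

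Candidate Pum2-associated transcripts should exceed both controls. Ranked by the smaller of the differences, Rtl6 (1.36 over IgG and 1.38 over input), Etv5 (1.90 and 1.33), Ifngr1 (1.501 and 1.25), Ncstn (1.24 and 1.17), the synaptic vesicle protein gene Sv2b (1.17 and 1.32), Nr4a1 (1.17 and 1.503), the haem synthesis gene Cpox (1.33 and 1.16), the glutamine transporter gene Slc38a3 (1.15 and 1.35) and Rab6b (1.37 and 1.14) were among the first. In all, 3148 genes (14.2%) were higher than both controls and 1706 (7.7%) lower than both, of which 890 and 794 differed at least 1.5-fold from each and 49 and 272 at least 2-fold. Among the 11090 genes at or above the median signal, 25.9% were higher than both. In the same set the share was 66.7% for reported Pumilio targets (14 of 21, Fisher's exact test, two-sided, adjusted p = 5.41e-04), 63.6% for the Notch pathway (14 of 22, adjusted p = 9.4e-04). It was 60.6% for cell-cycle genes (20 of 33, adjusted p = 2.35e-04), 60% for the Wnt pathway (18 of 30, adjusted p = 5.39e-04) and 59.1% for radial precursor genes (13 of 22, adjusted p = 0.00328). It was 2% for ribosomal protein genes (1 of 51, adjusted p = 8.79e-05), while 0 of 41 small nucleolar RNAs (adjusted p = 8.79e-05) and 0 of 27 olfactory and vomeronasal receptor genes (adjusted p = 0.00205) passed. No list of other cell types passed this test, which can miss a difference in lists with so few genes. Shares were 50% for ganglionic eminence (4 of 8), 46.7% for meningeal (7 of 15), 44.4% for microglial (4 of 9) and 40% for endothelial genes (6 of 15). Each of these lay above the 25.9% of all genes in the set, so a higher share was not particular to precursor and pathway lists. Cajal-Retzius and choroid plexus genes gave 2 of 11 and erythroid genes 0 of 8. The test treats genes as independent. Both comparisons use the same Pum2 arrays, which alone makes them correlate. Simulations of unchanged Pum2 arrays, 100 in number, hold no effects and so almost no calls, and their overlap of 0 genes shows no excess. Independent lists of these sizes would share 928 higher and 329 lower genes, a value that leaves out the shared arrays. The log2 differences correlated at 0.79 across genes against 0.50 in simulation, with a covariance of 0.144 against 0.00888. With 3 Pum2 arrays no split into parts of at least 2 could be made, so how much of the overlap the shared arrays give was not measured. Centring on the brighter genes kept 2238 of the 3148 genes, with 2201 lower than both. With all features of the table counted, 3364 were higher and 4397 lower than both, so which direction is more frequent depends on the features counted.

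**Figure D3:**
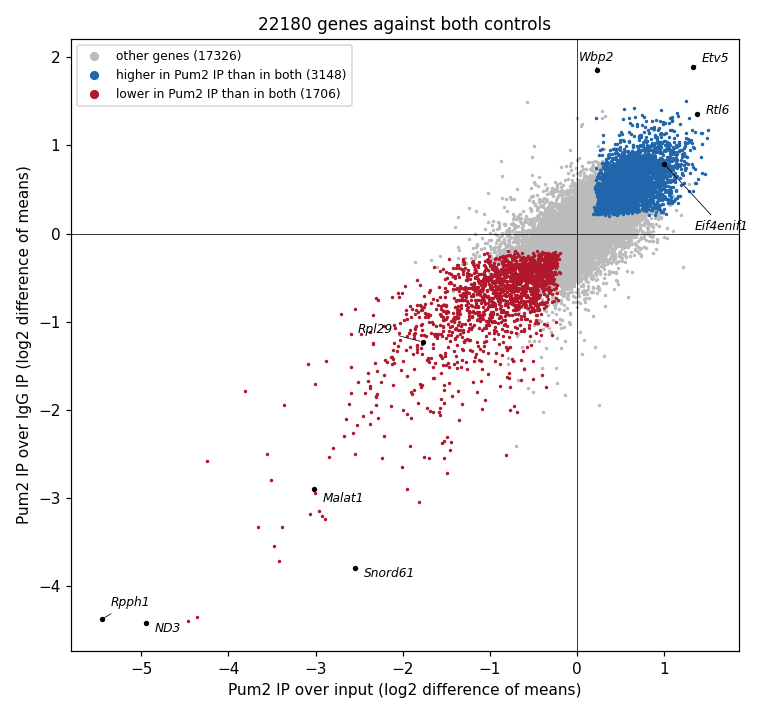
Each point is 1 of 22180 genes, placed by its log2 difference between Pum2 precipitate and input (horizontal) and between Pum2 precipitate and IgG precipitate (vertical); blue marks the 3148 genes higher and red the 1706 genes lower than both controls, and named genes are in black. Etv5 and Rtl6 lie at the upper right, Wbp2 at 1.86 over IgG but 0.22 over input, and ND3 and Rpph1 at the lower left.

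Some of the largest differences between the precipitates arose with a low IgG signal. Wbp2, a transcriptional coactivator, exceeded IgG by 1.86 ± 0.11 and input by 0.22 ± 0.11 (adjusted p = 3.88e-06 and 0.156), since its IgG signal lay below input (-1.64 ± 0.11). The histone gene H4f16 was 1.498 ± 0.12 above IgG and -0.58 ± 0.12 against input, and the E3 ligase gene Dtx3 1.42 ± 0.09 and 0.54 ± 0.09.

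IgG over input measures what the nonspecific antibody, the beads and the handling do to RNA composition. The histone gene H4f16 and Terc, the RNA of telomerase, fell (-2.08 ± 0.12 and -1.79 ± 0.30, adjusted p = 6.54e-05 and 0.00246), as did Rny1 (-1.66 ± 0.25). Gemin6, of the complex that assembles splicing particles, stood at -1.57 ± 0.14, and Uqcc2, an assembly factor of respiratory complex III, at -1.53 ± 0.08. Phxr4 rose most (2.20 ± 0.14, 4.61-fold, adjusted p = 6.54e-05), followed among others by the GABA receptor gene Gabra2 (1.58 ± 0.12), the semaphorin receptor gene Plxna4 (1.08 ± 0.12), the lipoprotein receptor gene Lrp1 (1.08 ± 0.10) and Runx1t1 (1.07 ± 0.09). Higher genes numbered 1829 and lower genes 2155, and 422 and 663 changed at least 1.5-fold. Calls were higher in 45.9% of cases, but in 51.5% with centring on the brighter genes (2105 higher and 1985 lower), so the more frequent direction depended on the scaling. Groups did not overlap for 32% of genes, against 10% by chance.

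Ribosomal protein mRNAs fell in IgG over input in 47 of 67 cases and rose in 1 (50 and 1 adjusted over the list alone; median -0.46, adjusted p = 1.02e-24, and 0.0231 with an estimated correlation), the sole list whose call held in that setting. Rplp0 fell by 1.38 ± 0.13. Oxidative phosphorylation genes fell in 49 of 71 cases and rose in 0 (52 and 0 adjusted over the list alone; median -0.55, adjusted p = 2.68e-27, but 0.0559 with an estimated correlation). Uqcr11 fell by 1.02 ± 0.07. Histone genes fell in 14 of 29 and rose in 0 (15 and 0 adjusted over the list alone; median -0.46, adjusted p = 1.22e-07, but 0.0559 with an estimated correlation). Higher were axon guidance genes, with 29 of 43 up and 0 down (31 and 0 adjusted over the list alone; median 0.40, adjusted p = 1.12e-14, but 0.0559 with an estimated correlation). Chromatin regulators had 20 of 36 up and 1 down (24 and 1 adjusted over the list alone; median 0.33, adjusted p = 1.32e-09, but 0.0559 with an estimated correlation). Deep-layer genes had 11 of 17 up and 0 down (12 and 0 adjusted over the list alone; median 0.36, adjusted p = 6.03e-06, but 0.0559 with an estimated correlation). Epha5 rose by 0.95 ± 0.08, Nrp2 by 0.88 ± 0.09, Arid2 by 0.80 ± 0.07, Crebbp by 0.80 ± 0.07 and Bcl11b, a determinant of subcortical projection neurons, by 0.86 ± 0.08. Upper-layer genes gave 5 and 0 of 13 (6 and 0 adjusted over the list alone; median 0.22, adjusted p = 0.00145, but 0.0751 with an estimated correlation). Proneural factors gave 5 and 1 of 18 (6 and 1 adjusted over the list alone; median 0.18, adjusted p = 0.00809, but 0.25 with an estimated correlation). Wnt pathway genes gave 8 and 0 of 32 (11 and 2 adjusted over the list alone; median 0.18, adjusted p = 0.00442, but 0.191 with an estimated correlation). The silencing machinery gave 11 and 1 of 35 (14 and 4 adjusted over the list alone; median 0.18, adjusted p = 0.00809, but 0.25 with an estimated correlation). Neuronal structure genes gave 10 and 3 of 26 (10 and 5 adjusted over the list alone; median 0.16, adjusted p = 0.0409, but 0.562 with an estimated correlation). This call ended without input replicate 2 (0.12) or IgG replicate 3 (0.12), with Pum2 left out of the fit (0.16), with centring on the brighter genes (0.19) and with the mean over features (0.16).

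The remaining cortical and RNA lists did not pass camera in IgG over input. They were reported Pumilio targets (6 up and 3 down of 22, also adjusted over the list alone; adjusted p = 0.434), radial precursor genes (4 and 4 of 22, or 10 and 4 adjusted over the list alone; adjusted p = 0.189), cell-cycle genes (4 and 0 of 33, also adjusted over the list alone; adjusted p = 0.0806), the Notch pathway (8 and 5 of 24, or 9 and 6 adjusted over the list alone; adjusted p = 0.108), ubiquitin genes (10 and 4 of 37, or 10 and 5 adjusted over the list alone; adjusted p = 0.109) and long noncoding RNAs (4 and 0 of 13, also adjusted over the list alone; adjusted p = 0.103). Small nucleolar RNAs split into 16 higher and 10 lower of 78 (18 and 15 adjusted over the list alone; median -0.03, mean 0.05, adjusted p = 0.739). The mitochondrially encoded genes, so low with Pum2, had a median of -0.04 here (adjusted p = 0.614), and 1 of the 10, ND6, was lower (-0.53 ± 0.16, adjusted p = 0.0468; 0 adjusted over the list alone). The ND6 call was lost without input replicates 1 and 2, IgG replicates 1 and 3 and Pum2 replicates 1 and 3, where the differences were -0.48, -0.47, -0.47, -0.49, -0.53 and -0.53. It was also lost with centring on the brighter genes (-0.50), with array weights (-0.54) and with a replicate block (-0.525). Without input replicate 1, or without IgG replicate 2, cell-cycle genes passed (0.13 and 0.09), and without IgG replicate 1 so did the Notch pathway (0.27). With quantile normalization run again radial precursor (0.19), cell-cycle (0.14), Notch (0.24) and ubiquitin genes (0.12) passed as higher, and fry, a self-contained test, passed radial precursor, Notch, ubiquitin and long noncoding RNA lists.

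Of 6 lists of cells that a dissected cortex can also hold, 2 passed camera against IgG, and none with an estimated correlation. With a replicate block the ganglionic eminence (0.254) and Cajal-Retzius lists (0.197) passed as well. Against IgG, endothelial and mural genes gave 9 higher and 1 lower of 20 (14 and 1 adjusted over the list alone; median 0.41, adjusted p = 0.0149, but 0.42 with an estimated correlation). Meningeal and mesenchymal genes gave 10 and 1 of 20 (10 and 2 adjusted over the list alone; median 0.39, adjusted p = 0.0149, but 0.337 with an estimated correlation). The tight junction gene Cldn5 rose by 1.00 ± 0.11, the mesenchymal factor Twist1 by 1.09 ± 0.09 and Vtn, a member of both lists, by 0.98 ± 0.12, while the pericyte gene Rgs5 fell by 0.71 ± 0.11. The endothelial call ended without IgG replicate 1 (median 0.34). Ganglionic eminence and interneuron genes gave 5 and 1 of 19, also adjusted over the list alone (median 0.25, adjusted p = 0.0878). Dlx5 rose by 1.14 ± 0.22 and the neuropeptide gene Sst by 1.42 ± 0.20. Cajal-Retzius and choroid plexus genes gave 3 and 0 of 18, also adjusted over the list alone (median 0.20, adjusted p = 0.107). Calb2 rose by 1.23 ± 0.12, and the list passed without Pum2 replicate 3 (0.33). Microglia and macrophage genes gave 5 and 1 of 19, also adjusted over the list alone (median 0.16, adjusted p = 0.448). Csf1r rose by 0.92 ± 0.18. No gene of the 11 erythroid ones passed in either direction, also adjusted over the list alone (median -0.06, adjusted p = 0.448). Against input the same lists gave 13 and 1 of 20 for endothelial genes (14 and 1 adjusted over the list alone; median 0.49, adjusted p = 0.0052, but 0.222 with an estimated correlation) and 15 and 0 of 20 for meningeal genes (17 and 0 adjusted over the list alone; median 0.47, adjusted p = 1.14e-04, but 0.108 with an estimated correlation). They gave 7 and 0 of 19 for ganglionic eminence genes, also adjusted over the list alone (median 0.23, adjusted p = 0.0174, but 0.129 with an estimated correlation) and 8 and 0 of 18 for Cajal-Retzius and choroid plexus genes (9 and 0 adjusted over the list alone; median 0.28, adjusted p = 0.0129, but 0.188 with an estimated correlation). Counts were 5 and 2 of 19 for microglia, also adjusted over the list alone (median 0.06, adjusted p = 0.759), and 0 and 3 of 11 for erythroid genes (0 and 2 adjusted over the list alone; median -0.11, adjusted p = 0.184). The embryonic globin gene Hbb-bh1 fell by 1.17 ± 0.27. Its difference from IgG, not past the threshold (-0.70, adjusted p = 0.0718), passed without IgG replicate 3 (-0.94) or Pum2 replicate 2 (-0.91), with only the brighter genes (-0.70), with quantile normalization run again (-0.765) and with centring (-0.80). It passed with a replicate block too (-0.704). In IgG over input, where none of these 6 lists passed camera (adjusted p of 0.129 to 0.528), the genes higher and lower were 4 and 1 endothelial, 6 and 1 meningeal, 2 and 2 of the ganglionic eminence, 4 and 1 Cajal-Retzius or choroid plexus, 1 and 0 microglial, and 0 and 0 erythroid. Adjusted over the list alone, the same counts were 4 and 2, 7 and 3, 3 and 2, 4 and 1, 1 and 0, and 0 and 0. Without input replicate 1 the Cajal-Retzius and choroid plexus list passed (0.16), and without IgG replicate 2 the erythroid list (-0.21).

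The 1390 olfactory and vomeronasal receptor genes, which embryonic cortex is not known to express, give the background of the calls. They were called in 95 cases (6.8%) against IgG, 80 (5.8%) against input and 67 (4.8%) in IgG over input. Against IgG 80 were lower and 15 higher (0 and 0 adjusted over the list alone), with a median of -0.06 (adjusted p = 0.00111, and 0.0341 with an estimated correlation), which became 0.11 with quantile normalization run again, when the median of all genes was 0.19. Against input 42 were higher and 38 lower (1 and 8 adjusted over the list alone; adjusted p = 0.1), and in IgG over input 57 and 10 (3 and 1 adjusted over the list alone; adjusted p = 0.0765, but passing without IgG replicate 3, at a median of 0.07).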

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

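All explanations in this part were chosen, and their tests written, only after the results had been seen. Features with no single gene name, which the comparisons of genes leave out, also carry signal. Of 17824 such features, 526 (3%) were higher in the Pum2 precipitate than in both controls and 2730 (15.3%) were lower than both. They were marked because they lie outside the named genes yet exceed the controls. Groups of 3 arrays were not tested for outliers.

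Mitochondrially encoded transcripts and small nucleolar RNAs were low in the Pum2 precipitate and, by list median, not in IgG. Centring on the brighter genes moved all genes alike, by -0.095, and left medians of -3.366 and -1.143. That shift is too small to give the pattern, but scaling that differs between genes was not excluded. Loss in any precipitation was not seen for the lists as a whole. Their medians were -0.043 or higher in IgG over input and, with 1 array left out, none below -0.102. For single members it was not excluded, since small nucleolar RNAs split there into 16 higher and 10 lower of 78. At most 1e-04 of 10000 random lists matched on level were as low, which is the smallest share they can give. The lowest random medians were -0.576 for the mitochondrial and -0.064 for the small nucleolar list. Level was the mean over all arrays, so it already held the drop with Pum2. ND4 had a mean of 12.292 but 13.262 to 13.465 on the input and IgG arrays. Random lists also hold unrelated genes, while the mitochondrial list had an estimated correlation of 0.61. Signal level was therefore not excluded. RNA kept out of the cytosol may escape an antibody to a cytosolic protein. Nuclear and imprinted long noncoding RNAs were also lower (camera adjusted p = 0.0341 with an estimated correlation), though only 5 of 13 genes were. That list mixes 2 kinds of RNA, and ribosomal protein mRNAs were lower than in IgG as well (median -0.204). The explanation is therefore not settled.

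Ribosomal protein and nuclear-encoded oxidative phosphorylation mRNAs were low in IgG over input. At most 1e-04 of random lists matched on level were as low. These lists hold unrelated genes, and the level was a mean that includes the IgG arrays. Signal level was therefore not fully excluded. Centring moved all genes alike, by 0.024, too little to give the pattern (weaker median -0.437). Scaling that differs between genes was not excluded. Transcript length was not tested, so whether short mRNAs are lost in any precipitation stays open.

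Reported Pumilio targets were higher in the Pum2 precipitate than in IgG. A share of 2e-04 of random lists matched on level was as high. These lists hold unrelated genes, and the level was a mean that includes the Pum2 arrays. Signal level was therefore not fully excluded. Centring moved all genes alike, by -0.095, and left a median of 0.417. Scaling that differs between genes was not excluded. Binding by Pum2 could explain the shift, but the motif test that would bear on it was not run.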

How the results depend on the processing

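The alternatives were planned before the values were seen. With 1 array left out, which leaves 2 arrays in a group, every count stayed within 1.5 times: 3594 to 4157 higher and 2050 to 2457 lower in Pum2 over IgG, 4072 to 4783 and 2528 to 2909 in Pum2 over input, 1334 to 1706 and 1707 to 2102 in IgG over input, and 2577 to 2948 and 1435 to 1618 against both. List medians in Pum2 over IgG then ranged from 0.137 to 0.224 (axon guidance), -0.108 to -0.051 (oxidative phosphorylation), 0.308 to 0.496 (endothelial) and 0.128 to 0.325 (Cajal-Retzius). Over all lists and comparisons 687 calls were the same, 8 lost and 7 gained; under the other settings 699, 57 and 24.

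Under other settings 66 counts stayed within 1.5 times and 22 moved further. Of the 111 named genes 102, 108 and 57 were called in Pum2 over IgG, Pum2 over input and IgG over input. Other settings lost 2, 0 and 10 of these calls and gained 5, 1 and 14, leaving out 1 array lost 5, 3 and 14 and gained 3, 1 and 7, and no called gene changed sign. Quantile normalization run again gave 8093 genes higher in Pum2 over IgG, 7845 over input and 5472 over both. It took the median of all genes from 0.043 to 0.192 against IgG and from 0.065 to 0.189 against input, and the share of calls that were higher from 63% and 62.3% to 79.1% and 76.6%; centring on the brighter genes took the medians to -0.051 and -0.005, and the shares to 46.9% and 52.2%. All features of the table gave 6481 lower than IgG (4877 higher), 6601 lower than input (5319 higher) and 4397 lower than both (3364 higher), so lower calls became the more frequent. An adjusted p with 1.5-fold left 1448 and 1106, 1844 and 1547, 422 and 663, and 890 and 794. An unadjusted p with 1.5-fold left 1455 and 1135, 1852 and 1566, 455 and 684, and 892 and 812.

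In Pum2 over IgG, camera with an estimated correlation ended the calls of radial precursor (0.346), cell cycle (0.361) and Notch genes (0.395). So it did for Wnt (0.402), axon guidance (0.183), ribosomal protein (-0.204) and oxidative phosphorylation genes (-0.079). The mitochondrially encoded (-3.271), endothelial (0.408) and meningeal calls (0.386) ended too. In this comparison p also rose for lists whose estimate lay below the preset 0.01. Unadjusted camera p went from 3.85e-04 to 0.00524 for olfactory genes (estimate 0.0067). For long noncoding RNAs (estimate -0.0359) it went from 7.31e-06 to 0.00317. The setting therefore changes more than the correlation, and the lost calls cannot be put down to correlation between genes alone. With only brighter genes, calls ended for cell cycle (0.361), Notch (0.407), axon guidance (0.183), endothelial (0.531) and meningeal genes (0.239). Quantile normalization again ended those of radial precursor (0.317), cell cycle (0.342), Notch (0.402), axon guidance (0.191) and meningeal genes (0.495), and made chromatin (-0.016) and ubiquitin genes (-0.041) pass as lower. With fry, neuronal structure (0.134), microglia (0.16), ganglionic eminence (0.254) and Cajal-Retzius genes (0.197) passed. In Pum2 over input, brighter genes only ended the calls of upper-layer (0.334), neuronal structure (0.334), silencing machinery (0.242) and long noncoding RNA lists (-0.672), and quantile normalization again those of the first 3 (0.369, 0.363 and 0.278), while fry passed proneural (0.235) and ubiquitin genes (0.263). In IgG over input, quantile normalization again passed radial precursor (0.191), cell-cycle (0.143), Notch (0.239) and ubiquitin genes (0.115), the intensity trend cell-cycle genes (0.087), and brighter genes only Notch (0.266), olfactory (0.232) and Cajal-Retzius genes (0.217). There fry passed radial precursor (0.15), Notch (0.22), ubiquitin (0.083), long noncoding RNA (0.06), olfactory (0.073) and meningeal lists (0.187). The cause was not tested.

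Labels of arrays of different groups share a number, and do not say whether it marks a shared sample. Same-number deviations correlated at 0.002 to 0.135 over 9 pairs, 3 of them over 0.1, against -0.13 to 0.041 for other pairs, and 8 of 9 arrays correlated best with their own number. With a replicate block 4344 genes were higher and 2521 lower in Pum2 over IgG, 3204 higher than both (2988 of the 3148 kept), and the ganglionic eminence (0.254) and Cajal-Retzius lists (0.197) passed. In Pum2 over input the block ended the call of the silencing machinery (0.242) and of no other list. Of gene calls the report gives, Hbb-bh1 in Pum2 over IgG (-0.704) passed as lower and ND6 in IgG over input (-0.525) no longer passed. The motif test was not run. Probes near background limit what dim genes can show.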

Other observations

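All lists and tests of this part were chosen after the data had been seen, and p-values are adjusted over the 5 lists added. Feedback and early-response genes of receptor tyrosine kinase signalling, such as Etv5 and Nr4a1, rose as a group with Pum2. The p-values and counts of the whole list include the 4 genes whose rise prompted it, so they partly restate that rise. Of 32 genes, 19 were higher and 0 lower than in IgG (22 and 0 adjusted over the list alone, median 0.50, camera adjusted p = 2.53e-08, and 0.00794 with an estimated correlation). Against input 21 were higher and 0 lower (25 and 0 adjusted over the list alone, median 0.46, adjusted p = 1.38e-08, and 0.0077 with an estimated correlation). In IgG over input the list did not pass camera (4 and 1, also adjusted over the list alone, adjusted p = 0.324) but passed fry (adjusted p = 0.0337). Whether transcripts of signal-induced genes are held with Pum2 as a group cannot be settled here. The other members, too, were chosen after the values had been seen, so the following share is no independent support. Without the 4 genes that prompted the list, 28 genes had a median of 0.393 against IgG. The highest of 10000 random lists matched on level reached 0.388, and the share is given as 1e-04, the smallest they can give. Of the 28 genes 15 were higher than both controls. The test cannot part binding from other properties such as short half-life.

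Host genes of small nucleolar RNAs were also lower with Pum2: 11 of 16 were lower and 1 higher than in IgG, also adjusted over the list alone (median -0.91, adjusted p = 1.71e-08, but 0.109 with an estimated correlation). Against input 11 were lower and 1 higher (12 and 1 adjusted over the list alone, median -1.148, adjusted p = 1.34e-09, but 0.0612 with an estimated correlation). The hosts also passed in IgG over input, with 5 lower and 1 higher (7 and 1 adjusted over the list alone, median -0.23, adjusted p = 0.00395, but 0.397 with an estimated correlation). The small nucleolar RNAs did not pass there, and a difference between the lists was not tested. Proteasome subunit genes rose over IgG, with 31 of 47 higher and 1 lower (31 and 2 adjusted over the list alone, median 0.35, adjusted p = 1.23e-05, but 0.177 with an estimated correlation), yet not over input (13 and 7, or 14 and 7 adjusted over the list alone, adjusted p = 0.964). In IgG over input 2 were higher and 21 lower (2 and 27 adjusted over the list alone, median -0.25, adjusted p = 1.86e-08, but 0.18 with an estimated correlation). Mitochondrial ribosomal protein genes fell in IgG over input, 62 of 71 with 0 higher (69 and 0 adjusted over the list alone, median -0.56, adjusted p = 3.08e-37, and 0.00929 with an estimated correlation), and showed no common shift between the precipitates (19 higher and 17 lower, or 19 and 19 adjusted over the list alone, adjusted p = 0.561). In Pum2 over input 49 were lower and 3 higher (51 and 3 adjusted over the list alone, median -0.46, adjusted p = 2.13e-19, and 0.0234 with an estimated correlation). Zinc finger genes of the Zfp family fell slightly against IgG, 86 of 370 with 49 higher (89 and 50 adjusted over the list alone, median -0.06, adjusted p = 0.00257, but 0.118 with an estimated correlation). Against input 84 were lower and 63 higher (86 and 64 adjusted over the list alone, median -0.03, adjusted p = 0.00764, but 0.124 with an estimated correlation and 0.0909 with fry). In IgG over input the list passed neither camera nor fry (31 lower and 39 higher, or 32 and 40 adjusted over the list alone, adjusted p = 0.791).

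Arrays were also regrouped. Only 1 of 10 splits of 3 against 3, the real one, gave as many genes in each comparison: 6815 in Pum2 over IgG, 7688 in Pum2 over input and 3984 in IgG over input, with 0 in every other split. Too few splits exist for a share under 0.05. For genes higher than both, 100 splits were used, the real one and others drawn at random from all possible ones. The real split gave 3148. The highest other count, 2504, came from the 1 other drawn split that keeps the 3 Pum2 arrays together, and drawn splits that part them gave at most 1320. Splits that mix the groups put the real differences into the spread, so their low counts do not measure chance.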
